A study of Mus musculus with 8 samples.

How the data were processed

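Polyadenylated RNA from primary mouse vascular smooth muscle cells was sequenced from 8 libraries in 4 groups of 2, per the labels. The cells overexpressed either THOC5 or green fluorescent protein (GFP), and were kept in growth medium or in osteogenic medium, which the series design names as inorganic phosphate for 6 days. Libraries were made with a TruSeq RNA kit that does not mark strand, per the labels, so reads from overlapping or antisense genes cannot be separated. The series design also names RNA immunoprecipitation sequencing, which was not analysed here. Groups follow the sample titles, and each table column was matched to its sample by the label's description field, so that 0 per-sample columns went unused. For THOC5 cells in growth medium the columns 502_S5 and 503_S6 were taken as replicates 1 and 2 through that field alone, though their names end in 2 and 3.

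The deposited table holds a signal for 27249 genes in each library, which is the gene's read count divided by 1 size factor per library, as tested on the values themselves. Multiplying each of the authors' values by its library's factor gave whole reads for 100% of values, with a largest distance of 1.34e-09 from a whole number. The deposited factors matched median-of-ratios factors of those reads to within a relative distance of 3.22e-15. The authors' deposited table also gives a log2 fold change and an adjusted p-value for 4 comparisons, per the file headers. Counting, trimming and the annotation are not given in the sources used here. FastQC, Bowtie2, MACS2, SAMtools and the mm10 genome are named without versions or roles, per the submitters' processing notes. Recovered reads numbered 8244941 and 7058681 in GFP cells in growth medium, and 9838885 and 9683045 in GFP cells in osteogenic medium. They numbered 10222637 and 10450335 in THOC5 cells in growth medium, and 10581042 and 10431562 in THOC5 cells in osteogenic medium. A count of 0 allows an expected count of up to 3 reads, which corresponded to between 2.59 and 3.99 normalized counts and covers counting error only.

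The tests, the 35 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. That design assumed read counts or per-million values. The table held size-factor-normalized counts, so the test planned for normalized values was used, and count models became alternatives on the recovered reads, chosen after seeing the data. limma 3.58.1 under R 4.3.3 was fitted with its trend option to log2 of the normalized count plus 1, for the 22575 genes with at least 1 in at least 2 libraries. All 8 libraries entered 1 fit with 4 groups and no block, which left 4 residual degrees of freedom. The fit gave 5 contrasts, which were the medium response in each kind of cell, THOC5 against GFP in each medium, and the interaction of both factors. Benjamini-Hochberg adjustment was applied per contrast with a threshold of 0.05. Fold changes on this scale understate genes with low counts. The p-values measure the spread between libraries, and because the labels do not say that replicates were separate cultures, that spread may be technical.

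Gene lists held 940 pairs of list and gene. They covered contractile smooth muscle genes, osteochondrogenic genes, calcification inhibitors, phosphate handling, extracellular matrix, matrix proteases, modulated smooth muscle markers, mRNA export, mRNA decay, immediate early genes, TGF-beta, Wnt, Notch and p53 targets, and the cell cycle. Further lists held integrated stress, interferon, NF-kB, NRF2, hypoxia, oxidative phosphorylation, cholesterol, autophagy, senescence, ion channel, ribosomal and mitochondrially encoded genes. Markers of macrophages, endothelium, adventitial fibroblasts, adipocytes, Schwann cells, striated muscle, mesothelium and erythroid cells served as signs of other cell types. Lists were tested with camera at a preset correlation of 0.01, adjusted over 170 tests, which were 34 lists in 5 contrasts. The erythroid list had 1 measured member, under the minimum of 5, and was not tested. No list passed camera with an estimated correlation, and fry, which asks whether a list's own genes move on balance, was run beside it.

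Named genes followed a fixed rule. For each pairwise contrast it took Thoc5, a core of contractile and osteogenic genes, and the 8 risen and 8 fallen genes with the largest log2 change among those past the threshold. These had to have the 2 libraries of 1 group beyond both of the other, a mean of at least 47.1 normalized counts (5 CPM) and a name that is not a predicted model. It added up to 4 members of each list with the smallest p, and for the interaction the 5 highest and 5 lowest genes. Gene coordinates came from GENCODE M21 on GRCm38, in which 26459 symbols were found.

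On simulated counts with the libraries' own means and totals, limma recovered 58.2% of 1.5-fold changes and 97.0% of 2-fold changes in the GFP response. In the THOC5 response it recovered 46.3% and 98.5%, in THOC5 against GFP 67.2% and 95.5% in growth medium, and 59.7% and 95.5% in osteogenic medium. For the interaction it recovered 16.4% and 80.6%. Genes with low counts were not covered, and recovery may be lower for genes that vary more than the trend. These simulations gave between 132 and 179 calls per contrast, and the adjustment is stricter where fewer genes pass. The shares therefore do not carry over to contrasts with other numbers of calls, and for the growth-medium contrast, with 1 call, recovery would be lower. In the real data the median 95% interval of a log2 change reached 0.26 to either side, and 0.37 for the interaction, over 10738 genes above the floor.

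Alternatives fixed in advance were TMM factors, the library total, any value above 0, a minimum of 5 in 2 libraries, pseudocounts of 0.1 and 0.01, only the 4 libraries compared, an absolute log2 change of at least 1, a replicate block, and each library left out in turn. Alternatives chosen after seeing the data were edgeR 4.0.16 quasi-likelihood with TMM or RLE factors, DESeq2 1.42.0, a minimum of 10, the removal of mitochondrial and the most abundant ribosomal RNA genes, a replicate block within growth medium, and list tests and overlaps with each library left out. Members of near-identical families (Ifi200, Oas1, Ifit3, Prl2c, Serpina3, Gsta and class I histocompatibility genes, and the Thoc2 copy Thoc2l) are uncertain, since their reads may have been split or discarded by the counting. Comparisons that share the GFP osteogenic libraries were set beside 100 simulated draws with no effect. The values of 1 gene are not reported here.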

Results

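RNA-seq of primary mouse vascular smooth muscle cells, the contractile cells of the artery wall, gave normalized read counts for 8 libraries in 4 groups of 2. The cells overexpressed THOC5, a subunit of the THO complex that couples transcription to the export of mRNA, or GFP as the control. Each kind of cell was kept in growth medium or in osteogenic medium with inorganic phosphate for 6 days, a model of arterial calcification. Recovered reads ranged from 7058681 to 10581042 per library, and genes with at least 1 read from 21217 to 22482. Values are normalized counts with their SD (n = 2 libraries), and log2 changes are given with their SE for 2 libraries against 2 from the limma fit. Members of a gene list not counted as changed did not pass the test.

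Thoc5 (chromosome 11, 4895320 to 4928867, GRCm38) was read first in every library, as a check of the labels. It stood at 458 and 471 normalized counts in GFP cells in growth medium, and at 650 and 615 in GFP cells in osteogenic medium. The THOC5 cells held 2155 and 1406 in growth medium, and 1780 and 1937 in osteogenic medium. The means were 464 ± 8.90, 632 ± 24.1, 1780.3 ± 529.7 and 1859 ± 111 in that order. Reads of the introduced and of the endogenous gene were not separated. Thoc5 was 3.74-fold higher with overexpression in growth medium (log2 1.90 ± 0.15, limma adjusted p = 0.00187) and 2.93-fold higher in osteogenic medium (log2 1.55 ± 0.15, adjusted p = 5.24e-05). Its own response to osteogenic medium did not pass in GFP cells (log2 0.44 ± 0.15, adjusted p = 0.0652) or in THOC5 cells (log2 0.09 ± 0.15, adjusted p = 0.960).

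**Figure D1:**
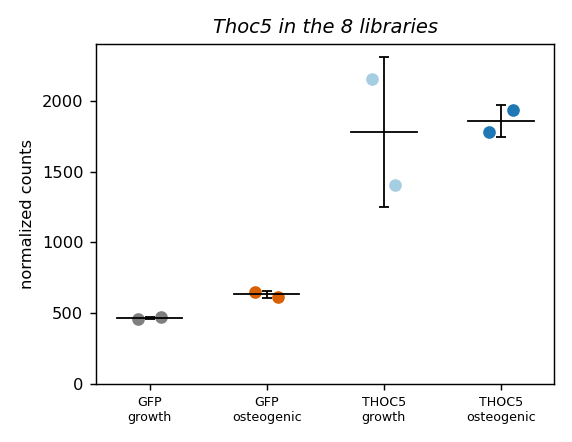
Normalized counts of Thoc5 in each library (points) by group, with the group mean as a line. The 4 THOC5 libraries lay between 1406 and 2155, above the 4 GFP libraries at 458 to 650.

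The 2 GFP libraries in osteogenic medium stood apart from the other 6. On the first principal component, with 76.3% of the variance, they lay at 49.2 and 38.5, and the other libraries between -10.7 and -21.2. Correlations across genes within a group, in which genes are not independent replicates, were 0.990 to 0.995. With the GFP osteogenic libraries left aside, correlations between groups were about as high, at 0.987 to 0.995. GFP growth replicate 1 correlated at 0.995 with THOC5 growth replicate 1 and at 0.990 with GFP growth replicate 2. The share of reads from mitochondrially encoded genes was 2.33 ± 0.0482% and 2.23 ± 0.00961% in growth medium for GFP and THOC5 cells, and 1.95 ± 0.0895% and 1.82 ± 0.108% in osteogenic medium. A ribosomal RNA gene, CT010467.1, took 2.60 ± 1.5% and 5.43 ± 1.19% in growth medium and 3.67 ± 0.0419% and 4.60 ± 0.349% in osteogenic medium.

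The osteogenic response of GFP cells addressed what the medium changes without added THOC5. Genes of the contractile apparatus and of the extracellular matrix fell, and genes of the oxidative stress, p53 and interferon responses rose. Mylk, the kinase that activates smooth muscle myosin, fell 6.77-fold (log2 -2.76 ± 0.18, limma adjusted p = 4.36e-06). Slc7a11, the cystine importer that feeds glutathione synthesis (chromosome 3, 49892526 to 50443614), rose 15.3-fold from 129.8 ± 40.6 to 1967 ± 328 normalized counts (adjusted p = 3.05e-05). Alpl, the tissue-nonspecific alkaline phosphatase of mineralizing cells (chromosome 4, 137741733 to 137796384), fell 4.80-fold from 62.8 ± 1.44 to 12.3 ± 1.54 (log2 -2.26 ± 0.22, adjusted p = 4.30e-05).

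Among the core genes, smooth muscle actin Acta2 (chromosome 19, 34241090 to 34255590) fell 2.07-fold from 21362 ± 2443 to 10332 ± 1192 normalized counts. Smooth muscle myosin heavy chain Myh11 (chromosome 16, 14194535 to 14291372) fell 3.44-fold, calponin Cnn1 2.37-fold and the matrix Gla protein gene Mgp, an inhibitor of calcification, 2.51-fold. Of these 4 genes and Alpl, every call was kept under each alternative setting that tested them. Tagln (transgelin) fell 1.61-fold (adjusted p = 0.00848), but its adjusted p was 0.106 without GFP growth replicate 1, 0.0663 without GFP osteogenic replicate 1, 0.0947 without GFP osteogenic replicate 2 and 0.0867 with only the 4 libraries compared. Runx2, the transcription factor of osteoblast commitment, fell 1.48-fold (adjusted p = 0.0131), with adjusted p of 0.157 and 0.0978 without GFP growth replicate 1 or 2, 0.173 without GFP osteogenic replicate 1, 0.0585 with only the 4 libraries and 0.0506 with any value above 0. Spp1 (osteopontin) rose 2.81-fold (adjusted p = 0.00587), with adjusted p of 0.0818 and 0.149 without GFP growth replicate 1 or 2, 0.107 with only the 4 libraries and 0.0763 by edgeR. Bmp2, a bone morphogenetic protein, had a log2 change of 1.51 ± 0.58 (adjusted p = 0.0931) and Sp7, an osteoblast transcription factor, -0.14 ± 0.56 (adjusted p = 0.907), and neither passed.

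Large rises among well-measured genes were in Oasl1 (15.6-fold), Rsad2 (9.10-fold) and Ifi208 (8.05-fold), which interferon induces, in the chemokine gene Cxcl10 (10.5-fold), and in Slc7a11. Prl2c2 (proliferin) rose 11-fold and the glutathione transferase gene Gsta3 8.25-fold. The largest falls were in Clca3a2 (46.5-fold; chromosome 3, 144796559 to 144819494) and in A2m (38.9-fold; chromosome 6, 121635376 to 121679227), which encodes the protease inhibitor alpha-2-macroglobulin. Serpina3i fell 19.0-fold, Kif26b 17.8-fold, secretogranin Scg2 16.3-fold, the axon guidance gene Draxin 15-fold, haptoglobin Hp 13.9-fold and Gdf6, of the bone morphogenetic protein family, 13.1-fold. Some of these sizes rest on few reads. The GFP osteogenic libraries held 2 and 6 for Serpina3i, 3 and 11 for Hp and 7 and 7 for Scg2. For Oasl1 the GFP growth libraries held 13 and 7.

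Contractile genes moved together, and 20 of 24 fell (20 fell and 1 rose adjusted over the list alone). The contractile median was -0.70 on the log2 scale (camera adjusted p = 6.83e-12, adjusted p = 0.239 with an estimated correlation), and the integrin Itga8 (-2.51 ± 0.21) fell beside Mylk. Of extracellular matrix genes 36 of 39 fell (37 fell adjusted over the list alone), including Col14a1 (-2.73 ± 0.15), Col6a1 (-1.75 ± 0.11) and tenascin Tnc (-2.26 ± 0.16). The matrix median was -1.06 (camera adjusted p = 2.76e-27, adjusted p = 0.239 with an estimated correlation). Of matrix proteases and their inhibitors 17 of 25 fell (18 fell adjusted over the list alone), such as Adam12 (-2.74 ± 0.15) and Adamts9 (-1.64 ± 0.12). The protease median was -0.72 (camera adjusted p = 1.44e-12, adjusted p = 0.239 with an estimated correlation). Of markers of adventitial fibroblasts, which moved with the matrix lists, 9 of 16 fell (12 fell adjusted over the list alone), among them C3 (-3.09 ± 0.18) and Lum (-3.06 ± 0.24). For the fibroblast list camera adjusted p = 8.32e-07, adjusted p = 0.239 with an estimated correlation. Of ion channel and calcium handling genes 12 of 30 fell and 2 rose (12 fell and 2 rose adjusted over the list alone). The channel median was -0.41 (camera adjusted p = 7.18e-04, adjusted p = 0.239 with an estimated correlation), with the regulator of G protein signalling Rgs5 at -1.73 ± 0.13. Of calcification inhibitors 5 of 14 fell and 1 rose (5 fell and 1 rose adjusted over the list alone). Their median was -0.46 (camera adjusted p = 0.0118, adjusted p = 0.357 with an estimated correlation), with Gas6 at -1.33 ± 0.13 and Fbln5 at -0.79 ± 0.11.

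Oxidative stress, p53 and interferon genes rose. Of NRF2 and oxidative stress genes 20 of 34 rose and 6 fell (21 rose and 6 fell adjusted over the list alone). The NRF2 median was 0.67 (camera adjusted p = 1.77e-07, adjusted p = 0.239 with an estimated correlation). These included the glutathione synthesis gene Gclm (2.39 ± 0.09), sulfiredoxin Srxn1 (2.26 ± 0.12), heme oxygenase Hmox1 (2.13 ± 0.11) and thioredoxin reductase Txnrd1 (1.90 ± 0.11). Of p53 targets 18 of 26 rose and 2 fell (18 rose and 2 fell adjusted over the list alone). The p53 median was 0.51 (camera adjusted p = 2.88e-08, adjusted p = 0.239 with an estimated correlation), with the p53 inhibitor Mdm2 at 1.44 ± 0.10 and the pro-apoptotic Pmaip1 at 1.67 ± 0.13. Of interferon response genes 38 of 43 rose (40 rose adjusted over the list alone), including Isg15 (1.46 ± 0.10), the chemokine Ccl5 (2.29 ± 0.11) and the nucleotide kinase Cmpk2 (2.78 ± 0.22). The interferon median was 0.94 (camera adjusted p = 3.78e-27, adjusted p = 0.292 with an estimated correlation). Of integrated and ER stress genes 14 of 34 rose and 2 fell (15 rose and 3 fell adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.00289, adjusted p = 0.254 with an estimated correlation). By edgeR only 7 of them rose and 3 fell, and by DESeq2 12 and 3, and the list differed by 0.44 between both GFP growth replicates. Of nuclear oxidative phosphorylation genes 15 of 65 rose (15 rose adjusted over the list alone), with cytochrome c, Cycs, at 1.79 ± 0.17. This list's median was 0.17 (camera adjusted p = 1.47e-05, adjusted p = 0.662 with an estimated correlation). Mitochondrially encoded genes went the other way, beside the lower mitochondrial share of reads in osteogenic medium, and 5 of 8 fell (5 fell adjusted over the list alone). Their median was -0.72 (camera adjusted p = 1.29e-04, adjusted p = 0.366 with an estimated correlation).

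Lists of RNA handling genes had small upward medians. For comparison, 2314 of all 22575 tested genes rose by limma, a share close to that of the ribosomal protein list. Of THO and TREX export genes, the machinery to which THOC5 belongs, 7 of 22 rose and 1 fell (10 rose and 1 fell adjusted over the list alone). The export median was 0.17 (camera adjusted p = 0.00171, adjusted p = 0.357 with an estimated correlation), with the export helicase Ddx39 at 1.01 ± 0.12 and the cap-binding Ncbp1 at 0.83 ± 0.10. Of mRNA decay genes 11 of 40 rose and 3 fell (12 rose and 3 fell adjusted over the list alone). The decay median was 0.17 (camera adjusted p = 0.00580, adjusted p = 0.240 with an estimated correlation), with the exosome subunits Exosc1 at 1.19 ± 0.16 and Dis3 at 0.69 ± 0.10. Of cytosolic ribosomal protein genes 7 of 57 rose (7 rose adjusted over the list alone), while edgeR called 16 higher and 1 lower and DESeq2 11 higher. The ribosomal median was 0.16 (camera adjusted p = 7.20e-04, adjusted p = 0.744 with an estimated correlation).

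Signalling lists were mixed. Of TGF-beta targets 10 of 21 fell and 2 rose (11 fell and 4 rose adjusted over the list alone). The TGF-beta median was -0.23 (camera adjusted p = 3.66e-04, adjusted p = 0.249 with an estimated correlation), with Ltbp2 at -2.05 ± 0.10 and Tgfbi at -1.81 ± 0.11. Of Wnt targets and modulators 9 of 22 fell and 2 rose (11 fell and 3 rose adjusted over the list alone). The Wnt median was -0.42 (camera adjusted p = 0.00290, adjusted p = 0.239 with an estimated correlation), with the secreted modulator Sfrp2 at -3.25 ± 0.18. Of senescence genes 8 of 19 fell and 3 rose (10 fell and 3 rose adjusted over the list alone). The senescence median was -0.43 (camera adjusted p = 0.0344, adjusted p = 0.254 with an estimated correlation). Of modulated smooth muscle markers 5 of 15 fell and 3 rose (5 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.0301, adjusted p = 0.357 with an estimated correlation). Their median went from -0.14 to 0.00 when libraries were scaled to their totals. Of cholesterol synthesis genes 5 of 25 fell and 1 rose (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0285, adjusted p = 0.679 with an estimated correlation). Of Schwann cell markers 2 of 8 fell (2 fell adjusted over the list alone, camera adjusted p = 0.0220, adjusted p = 0.252 with an estimated correlation).

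Further lists did not pass camera in this response. Of osteochondrogenic genes 4 of 21 rose and 6 fell (6 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.496), and by edgeR and DESeq2 2 rose and 6 fell. Of phosphate handling genes 2 of 11 rose and 2 fell (2 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.894), and the phosphate importer Slc20a1 rose by 0.86 ± 0.14. Of cell cycle genes 19 of 45 fell and 8 rose (21 fell and 9 rose adjusted over the list alone, camera adjusted p = 0.0867). Of immediate early genes 7 of 21 rose and 3 fell (9 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.194). Of NF-kB and acute inflammatory genes 12 of 30 fell and 6 rose (13 fell and 6 rose adjusted over the list alone, camera adjusted p = 0.113). Of Notch targets 3 of 10 fell (5 fell adjusted over the list alone, camera adjusted p = 0.0709). Of hypoxia genes 4 of 31 rose and 3 fell (4 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.401), and by edgeR 4 rose and 0 fell. Of autophagy and lysosome genes 8 of 32 rose and 3 fell (9 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.435). Of macrophage markers 3 of 13 rose and 2 fell (4 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.732). Of endothelial markers 1 of 9 fell (1 fell adjusted over the list alone, camera adjusted p = 1), with a median of 0.24, a mean of 0.07 and a downward test direction. Of adipocyte markers 2 of 7 rose and 1 fell (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.384). Of striated muscle markers 1 of 9 rose (0 adjusted over the list alone, camera adjusted p = 0.933), with a median of -0.10 (0.03 when scaled to library totals), a mean of -0.02 and an upward test direction. Of mesothelial markers 3 of 9 fell and 1 rose (3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.645). The erythroid list had 1 measured member, which did not pass and had no list test.

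By limma, 4698 genes passed in GFP cells, of which 2314 rose and 2384 fell, and 1239 changed at least 2-fold (494 higher and 745 lower). Scaled to library totals, 5409 passed with 3721 higher and 1688 lower, and the median of all genes moved by 0.141 on the log2 scale. The count was 2467 without GFP growth replicate 1, 2116 without GFP growth replicate 2, 2067 without GFP osteogenic replicate 1, and 2293 in a fit of only the 4 libraries. The authors' deposited table calls 3798 genes, of which 3725 also passed here, all with the same sign. With some library left out, camera no longer passed for calcification inhibitors, modulated smooth muscle markers, cholesterol, senescence, ribosomal protein and Schwann cell genes.

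In THOC5 cells the genes that rose most in osteogenic medium were interferon-inducible. Isg15, an interferon-induced ubiquitin-like modifier, rose 3.39-fold from 501 ± 54.1 to 1696 ± 83.9 normalized counts (log2 1.76 ± 0.10, limma adjusted p = 2.64e-05). Ifi208 rose 12.8-fold (adjusted p = 1.25e-04), Irf7 4.26-fold (adjusted p = 2.97e-05) and the class I histocompatibility gene H2-K1 2.20-fold (adjusted p = 9.39e-05). Among genes above the floor on the mean of all 8 libraries, large rises were also found in Ifi206 (3.32 ± 0.24), the antiviral Rsad2 (2.57 ± 0.28) and Ifit3 (2.46 ± 0.26). Ifit3b (2.49 ± 0.19), Oasl1 (2.31 ± 0.36) and Oas1g (2.14 ± 0.29) rose as well. Some sizes rest on few reads, as the THOC5 growth libraries held 6 and 7 for Ifi208 and 11 and 5 for Oasl1. By limma the 2 genes that fell were Ifi27 (log2 -1.44 ± 0.15, adjusted p = 7.75e-04), itself an interferon-inducible gene, and the mitochondrial cytochrome b gene mt-Cytb (-0.57 ± 0.10, adjusted p = 0.0218).

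Of interferon response genes 39 of 43 rose (42 rose adjusted over the list alone) in THOC5 cells. The interferon median was 1.30 (camera adjusted p = 3.85e-129, adjusted p = 0.239 with an estimated correlation). Of markers of other cells, the macrophage gene Mpeg1 (1.62 ± 0.17) and the fibroblast list's Ly6a (0.92 ± 0.12) and Ly6c1 (0.76 ± 0.12) rose with them. The contractile list had a median of -0.20 (camera adjusted p = 3.35e-07, adjusted p = 0.252 with an estimated correlation). Of its members 0 passed by limma, 7 were lower at an unadjusted p under 0.05, 0 by edgeR and 2 lower by DESeq2, and 3 fell adjusted over the list alone. Acta2 had a log2 change of -0.26 ± 0.12 (adjusted p = 0.872), Alpl of -0.08 ± 0.22, Mgp of -0.02 ± 0.11 and Slc7a11 of -0.51 ± 0.35 (adjusted p = 0.928), and none of them passed. The hypoxia and glycolysis list had a median of 0.29 (camera adjusted p = 1.62e-10, adjusted p = 0.470 with an estimated correlation). Of these genes 0 passed by limma, edgeR or DESeq2, and 6 had an unadjusted p under 0.05. Its members also differed between the growth replicates of each cell kind, with medians of -0.45 and -0.42 for replicate 1 against 2 in GFP and THOC5 cells. Of mitochondrially encoded genes 1 fell (6 adjusted over the list alone, 3 by edgeR and 5 by DESeq2), with a median of -0.40 (camera adjusted p = 2.07e-10, adjusted p = 0.239 with an estimated correlation), beside the lower mitochondrial share in osteogenic medium. The ion channel list had a median of -0.23 (camera adjusted p = 3.69e-04, adjusted p = 0.239 with an estimated correlation). The matrix list had -0.12 (camera adjusted p = 2.10e-04, adjusted p = 0.604 with an estimated correlation). The ribosomal protein list had -0.06 (camera adjusted p = 0.00231, adjusted p = 0.746 with an estimated correlation). The cell cycle list had 0.13 (camera adjusted p = 0.00656, adjusted p = 0.746 with an estimated correlation). The p53 list had 0.06 (camera adjusted p = 0.00656, adjusted p = 0.362 with an estimated correlation). The NF-kB list had 0.07 (camera adjusted p = 0.0128, adjusted p = 0.485 with an estimated correlation).

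In THOC5 cells 122 genes passed by limma, of which 120 rose and 2 fell, and 69 changed at least 2-fold. Of the 120, 39 belonged to the interferon list and 81 did not. The count fell to 8 without GFP growth replicate 1, 8 without GFP growth replicate 2, 44 without THOC5 growth replicate 2, 14 without THOC5 osteogenic replicate 1 and 18 without THOC5 osteogenic replicate 2. A fit of only the 4 libraries called 0 by limma, with 1788 at an unadjusted p under 0.05. On all 8 libraries edgeR called 156 (88.5% higher) and DESeq2 149 (88.6% higher), so falls were less rare than by limma. With any value above 0 limma called 37. Isg15, Ifi208, Irf7 and H2-K1 lost their calls in the 4-library fit alone (adjusted p = 0.332), and the other 11 genes named with a change also when at least 1 library was left out. The authors' deposited table calls 149 genes, 132 higher and 17 lower, of which 121 also passed here with the same sign. With some library left out, camera no longer passed for hypoxia, cell cycle, matrix, p53, ribosomal protein and NF-kB genes in THOC5 cells.

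Set side by side, both kinds of cell raised interferon genes in osteogenic medium, while most other genes of the GFP response did not pass in THOC5 cells. Both responses were past the threshold in the same direction for 97 genes by limma, of which 95 rose (12.3 from independent lists, Fisher's exact p = 5.76e-71) and 2 fell. Genes are not independent replicates, and both lists come from 1 fit that pools the spread of all 8 libraries. The Fisher p therefore cannot be read as the strength of a shared response. By edgeR 121 genes were shared, of which 103 rose, and by DESeq2 116, of which 100 rose. Of the 95, 36 belonged to the interferon list and 59 did not. The 97 were 8 without either GFP growth replicate, 56 without GFP osteogenic replicate 2, 41 without THOC5 growth replicate 2, 14 and 17 without THOC5 osteogenic replicate 1 or 2, and 0 with only the 4 libraries. The 36 were 4, 27, 24, 7, 10 and 0 in that order. Interferon list members had a median ratio of 1.31 between the THOC5 and the GFP log2 change over 38 members. The 4660 genes of the GFP response outside that list had a median ratio of 0.0307, and 55.1% had the same sign in both. Of the 4723 genes past the threshold in either response, 55.6% had the same sign in both, and the median ratio was 0.0338. Across these genes, which are not independent replicates, Pearson's r was 0.274 (0.417 without GFP growth replicate 2, 0.464 without GFP osteogenic replicate 1, 0.124 without THOC5 growth replicate 2, 0.182 without THOC5 osteogenic replicate 1 and 0.0738 over all tested genes). These 2 responses share no library, but their calls share the spread estimated from all 8 libraries. The median ratio of 0.0338 was 0.0597 without GFP growth replicate 2, 0.0657 without GFP osteogenic replicate 1, 0.0817 without THOC5 growth replicate 1, -0.00435 without THOC5 growth replicate 2, -0.00585 without THOC5 osteogenic replicate 1 and 0.0820 without THOC5 osteogenic replicate 2, and 0.00857 over all tested genes.

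**Figure D2:**
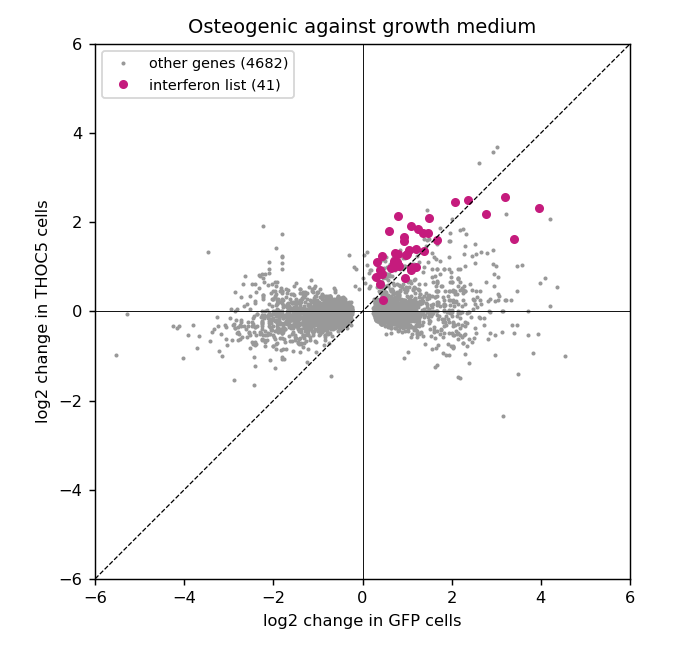
Log2 change in osteogenic against growth medium in GFP cells (horizontal) and THOC5 cells (vertical) for genes past the limma threshold in either, with the line of equal change dashed. Most of the 41 interferon genes rose in both, above or below that line, and the 4682 other genes mostly spread along the horizontal axis.

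**Figure D3:**
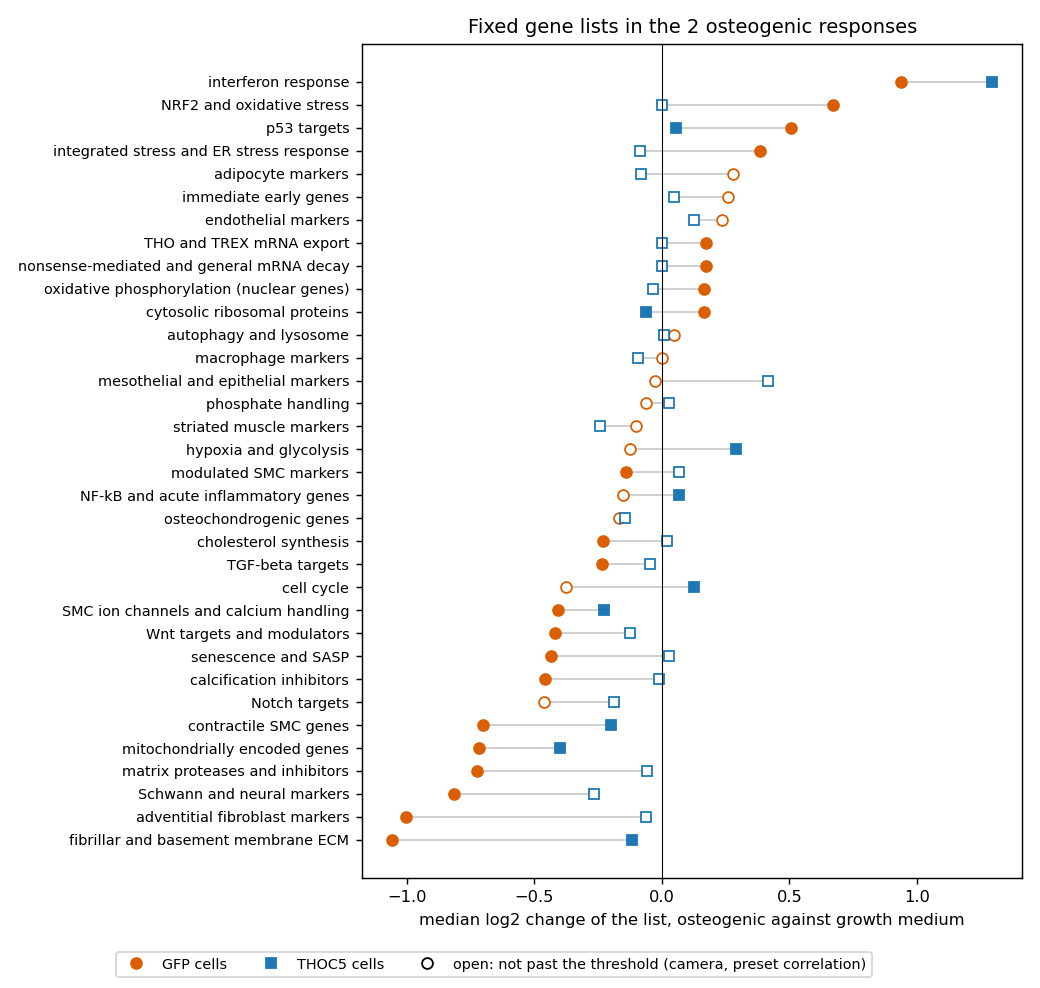
Median log2 change of each gene list in osteogenic against growth medium, for GFP cells (circles) and THOC5 cells (squares), filled where camera with the preset correlation passed. Interferon genes had medians of 0.94 and 1.30, and matrix genes of -1.06 and -0.12.

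In growth medium, THOC5 against GFP cells addressed what THOC5 changes without osteogenic medium, and Thoc5 itself was the single gene past the threshold. Camera, which sets a list against other genes, passed 12 lists here, and fry, which asks about a list's own genes, called 1. Against other genes, interferon response genes were lower in THOC5 cells, with a median log2 change of -0.28 (camera adjusted p = 2.21e-23, adjusted p = 0.322 with an estimated correlation). Singly 0 of them passed by limma, edgeR or DESeq2, 19 were lower at an unadjusted p under 0.05, and 8 fell adjusted over the list alone. This list was 0.36 higher in THOC5 growth replicate 1 than in replicate 2, as in Ifit3 (1144 and 556 reads) and Rsad2 (341 and 157), so 1 library carried much of the difference. Without THOC5 growth replicate 2 the median was -0.12 (camera adjusted p = 6.96e-05), and without replicate 1 it was -0.43. Higher against other genes were ribosomal protein genes, with a median of 0.14 (camera adjusted p = 1.92e-14, adjusted p = 0.479 with an estimated correlation). Nuclear oxidative phosphorylation genes had 0.11 (camera adjusted p = 1.15e-09, adjusted p = 0.494 with an estimated correlation). Contractile genes had 0.09 (camera adjusted p = 6.03e-04, adjusted p = 0.369 with an estimated correlation). Matrix genes had 0.14 (camera adjusted p = 6.64e-05, adjusted p = 0.570 with an estimated correlation). Wnt genes had 0.16 (camera adjusted p = 0.00110, adjusted p = 0.239 with an estimated correlation), and 2 rose adjusted over the list alone. Fibroblast markers had 0.18 (camera adjusted p = 0.0204, adjusted p = 0.452 with an estimated correlation). Cholesterol genes had 0.08 (camera adjusted p = 0.0398, adjusted p = 0.691 with an estimated correlation). Lower against other genes were p53 targets, at -0.11 (camera adjusted p = 0.00259, adjusted p = 0.336 with an estimated correlation). Immediate early genes had -0.09 (camera adjusted p = 0.00819, adjusted p = 0.275 with an estimated correlation). Hypoxia genes had -0.08 (camera adjusted p = 0.0124, adjusted p = 0.744 with an estimated correlation). NF-kB genes had -0.08 (camera adjusted p = 0.0344, adjusted p = 0.570 with an estimated correlation), and 2 fell adjusted over the list alone. Acta2 had a log2 change of 0.24 ± 0.12 (adjusted p = 0.906) and Alpl of 0.19 ± 0.22 (adjusted p = 0.953).

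The count of 1 in growth medium stood beside 1152 genes at an unadjusted p under 0.05, and edgeR called 4 and DESeq2 1. With no difference at all, a share near 0.05 of the 22575 tested genes would be expected there. The 1152 are close to that share and are no sign of further changed genes. The 4 by edgeR were Thoc5, Scg2, Gdf6 and Nkd1, the last of which was named after its values were seen. By edgeR the log2 changes were 0.98 for Scg2, 0.96 for Gdf6 and 1.14 for Nkd1. The single limma call thus does not show that no other gene differed about 2-fold. Thoc5 had an edgeR adjusted p of 0.0241, and its limma adjusted p was 0.635 and 0.928 without GFP growth replicate 1 or 2, 0.207 without GFP osteogenic replicate 1 and 0.207 without replicate 2. It was 0.0813 and 0.0820 without THOC5 osteogenic replicate 1 or 2, 0.811 with only the 4 libraries, 0.377 with any value above 0 and 0.186 with a pseudocount of 0.01. In those 9 settings limma called 0 genes, with 1738, 1068, 1332, 1336, 1024, 1028, 1252, 1660 and 1224 at an unadjusted p under 0.05 in that order, and the log2 change of Thoc5 stayed between 1.88 and 1.92. The authors' deposited table also calls 1 gene. With some library left out, camera no longer passed for contractile, matrix, Wnt, fibroblast, cholesterol, immediate early and NF-kB genes. The hypoxia median changed sign, to 0.11 without GFP growth replicate 2 and 0.12 without THOC5 growth replicate 1.

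In osteogenic medium THOC5 cells differed widely from GFP cells, with contractile and matrix genes higher and oxidative stress and p53 genes lower. Acta2 was 2.04-fold higher, at 21034 ± 1312 against 10332 ± 1192 normalized counts (log2 1.03 ± 0.12, limma adjusted p = 1.27e-04), and Myh11 2.90-fold higher (log2 1.53 ± 0.18, adjusted p = 1.79e-04). Alpl was 5.18-fold higher, at 67.9 ± 6.13 against 12.3 ± 1.54 (adjusted p = 2.80e-05), and Mgp 3.06-fold higher (adjusted p = 4.43e-06). Slc7a11 was 28.6-fold lower, at 67.7 ± 10.9 against 1967 ± 328 (log2 -4.84 ± 0.35, adjusted p = 8.33e-06). Cnn1 was 2.37-fold higher (adjusted p = 2.91e-05), while Spp1 (-0.95 ± 0.31, adjusted p = 0.0513), Runx2 (0.33 ± 0.14, adjusted p = 0.113), Bmp2 (-0.80 ± 0.58, adjusted p = 0.395) and Sp7 (0.25 ± 0.56) did not pass. Tagln was 1.44-fold higher (adjusted p = 0.0308), but its adjusted p was 0.122 and 0.204 without GFP osteogenic replicate 1 or 2, 0.0893 and 0.249 without THOC5 osteogenic replicate 1 or 2, and 0.119 scaled to library totals. For Tagln it was also 0.0546 with only the 4 libraries, 0.0887 with any value above 0, and 0.0518 and 0.0705 with pseudocounts of 0.1 and 0.01.

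The 8 largest differences upward were in the same 8 genes that fell most in GFP cells, led by Clca3a2 (40.3-fold), A2m (36.5-fold), Kif26b (20.4-fold) and Serpina3i (19.8-fold). Both rankings use the same GFP osteogenic libraries, so this overlap is partly built in. The largest differences downward were in Slc7a11, in Prl2c2 (7.22-fold), in the glutathione transferases Gsta3 (7.08-fold) and Gsta4 (6.70-fold), and in the stress genes Cth (7.34-fold), Atf3 (7.13-fold), Chac1 (6.88-fold) and Mthfd2 (6.76-fold). Each of these last 4 calls was lost when certain libraries were left out. Without GFP osteogenic replicate 1 or THOC5 osteogenic replicate 2, the limma adjusted p was 0.0592 and 0.0504 for Atf3, 0.150 and 0.133 for Cth, 0.210 and 0.108 for Chac1, and 0.113 and 0.0822 for Mthfd2. Without GFP osteogenic replicate 2 or THOC5 osteogenic replicate 1 it was 0.0920 and 0.0791 for Cth, 0.125 and 0.191 for Chac1, and 0.0676 and 0.0742 for Mthfd2. It was 0.0503 for Cth without GFP growth replicate 1, and 0.0592 and 0.0589 for Chac1 without GFP growth replicate 1 or 2, and by edgeR 0.121 for Chac1 and 0.0775 for Mthfd2. With any value above 0 it was 0.0635 for Cth and 0.0969 for Chac1, and with a pseudocount of 0.01 it was 0.0518 and 0.0764.

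Of contractile genes 17 of 24 were higher (19 were higher and 1 lower adjusted over the list alone) with THOC5. The contractile median was 0.59 (camera adjusted p = 5.02e-10, adjusted p = 0.239 with an estimated correlation), with Mylk at 2.77 ± 0.18. Of matrix genes 36 of 39 were higher (37 were higher adjusted over the list alone), including Col14a1 (2.75 ± 0.15) and Col6a1 (1.82 ± 0.11). The matrix median was 1.06 (camera adjusted p = 1.79e-26, adjusted p = 0.239 with an estimated correlation). Of matrix proteases 17 of 25 were higher (17 were higher adjusted over the list alone, camera adjusted p = 4.20e-12, adjusted p = 0.239 with an estimated correlation). Of adventitial fibroblast markers, which moved with the matrix lists, 13 of 16 were higher (14 were higher adjusted over the list alone, camera adjusted p = 5.71e-10, adjusted p = 0.239 with an estimated correlation). Of NRF2 and oxidative stress genes 19 of 34 were lower and 7 higher (21 were lower and 7 higher adjusted over the list alone), including Gclm (-2.59 ± 0.09) and Hmox1 (-2.08 ± 0.11). The NRF2 median was -0.87 (camera adjusted p = 3.94e-07, adjusted p = 0.239 with an estimated correlation). Of p53 targets 17 of 26 were lower and 2 higher (19 were lower and 3 higher adjusted over the list alone, camera adjusted p = 1.13e-07, adjusted p = 0.239 with an estimated correlation). Their member Pmaip1 was at -2.10 ± 0.13. Of integrated and ER stress genes 16 of 34 were lower and 5 higher (18 were lower and 6 higher adjusted over the list alone, camera adjusted p = 0.00276, adjusted p = 0.254 with an estimated correlation). The serine synthesis gene Psat1 was at -1.98 ± 0.27. Of TGF-beta targets 11 of 21 were higher and 4 lower (12 were higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00329, adjusted p = 0.303 with an estimated correlation). Of Wnt genes 10 of 22 were higher and 2 lower (11 were higher and 2 lower adjusted over the list alone, camera adjusted p = 7.64e-04, adjusted p = 0.239 with an estimated correlation). Of modulated smooth muscle markers 7 of 15 were higher and 2 lower (8 were higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00234, adjusted p = 0.249 with an estimated correlation). Of cell cycle genes 17 of 45 were higher and 6 lower (21 were higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.780 with an estimated correlation). Cyclin Ccnb2 was at 1.07 ± 0.12.

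Smaller shifts in osteogenic medium were found in other lists. Of calcification inhibitors 5 of 14 were higher and 1 lower (5 were higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0395, adjusted p = 0.465 with an estimated correlation). Of senescence genes 9 of 19 were higher and 3 lower (10 were higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.243 with an estimated correlation). Of hypoxia genes 5 of 31 were higher and 1 lower (5 were higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00956, adjusted p = 0.744 with an estimated correlation). Of cholesterol genes 7 of 25 were higher (7 were higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00944, adjusted p = 0.662 with an estimated correlation). Of ion channel genes 11 of 30 were higher and 2 lower (11 were higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00825, adjusted p = 0.239 with an estimated correlation), and their median went from 0.13 to -0.01 when scaled to library totals. Of export genes 7 of 22 were lower and 2 higher (9 were lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.479 with an estimated correlation). Of mRNA decay genes 12 of 40 were lower and 4 higher (14 were lower and 4 higher adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.272 with an estimated correlation). Of nuclear oxidative phosphorylation genes 7 of 65 were lower (7 were lower adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.746 with an estimated correlation). Of interferon genes 6 of 43 were lower and 3 higher (6 were lower and 3 higher adjusted over the list alone), and the list did not pass (camera adjusted p = 0.927). Its median was 0.07, its mean -0.09 and its test direction downward, and scaled to library totals the median was -0.10 with 11 lower and 1 higher. Of osteochondrogenic genes 5 of 21 were higher and 3 lower (5 were higher and 4 lower adjusted over the list alone, camera adjusted p = 0.542), with a median of 0.03 that went to -0.05 under the same scaling.

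By limma 4963 genes passed between THOC5 and GFP cells in osteogenic medium, of which 2550 were higher and 2413 lower, and 1329 differed at least 2-fold (769 higher and 560 lower). Scaled to library totals, 5728 passed with 1662 higher and 4066 lower, and the median of all genes moved by -0.171 on the log2 scale. The count was 2382 without GFP osteogenic replicate 1, 2852 without THOC5 osteogenic replicate 1, 1987 without THOC5 osteogenic replicate 2, and 3030 with only the 4 libraries. The authors' deposited table calls 4182 genes, of which 4101 also passed here with the same sign. Past the threshold in both media was 1 gene, Thoc5 (0.113 from independent lists, Fisher's exact p = 0.113), and by limma 0 without each of the 6 libraries whose removal ended its call in growth medium. Of genes above the floor, 56.8% had the same sign in both media. With some library left out, camera no longer passed for calcification inhibitors or for cell cycle, hypoxia, cholesterol, nuclear oxidative phosphorylation and export genes in osteogenic medium.

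Genes that moved in GFP cells in osteogenic medium differed in the opposite direction in THOC5 cells. Of the 4698 genes of the GFP response, 3794 (80.8%) passed in the opposite direction for THOC5 against GFP in osteogenic medium and 3 in the same direction. The 3794 were 2179 and 1917 without GFP growth replicate 1 or 2, 1679 without GFP osteogenic replicate 1, 2431 and 1862 without THOC5 osteogenic replicate 1 or 2, and 1772 with only the 4 libraries. The share was 48.6% without THOC5 osteogenic replicate 2 and from 63.4 to 90.6% without another library. Of the 3794, 1757 had risen in GFP cells (247 from independent lists) and 2037 had fallen (269 from independent lists). Both contrasts use the GFP osteogenic libraries, so these lists are not independent and those expectations are no baseline for them. Across genes, which are not independent replicates, the correlation was -0.94 and the covariance -0.297. With no effect, the shared GFP osteogenic libraries alone gave -0.50 and -0.00996 on average over 100 draws. The draws hold the spread between the shared libraries, but not a shift common to both of them, which would enter both contrasts.

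The interaction, which asks directly whether the osteogenic response differs between THOC5 and GFP cells, passed for contractile, matrix and oxidative stress genes. The difference of log2 changes was 0.79 ± 0.17 for Acta2 (limma adjusted p = 0.0138), 1.32 ± 0.26 for Myh11 (0.0107), 1.06 ± 0.16 for Cnn1 (0.00286), 2.18 ± 0.30 for Alpl (0.00188) and 1.31 ± 0.15 for Mgp (8.05e-04). The highest values were in A2m (5.22 ± 0.53), Clca3a2 (4.57 ± 0.49), Serpina3i (3.92 ± 0.51), Kif26b (3.79 ± 0.32) and Hp (3.50 ± 0.57). Among the lowest were Slc7a11 (-4.44 ± 0.50), the stress-induced Atf3 (-2.81 ± 0.70), Gsta3 (-2.66 ± 0.42) and the serine synthesis gene Psph (-2.49 ± 0.46). Of matrix genes 28 of 39 were higher (33 were higher adjusted over the list alone) relative to GFP cells (camera adjusted p = 4.09e-25, adjusted p = 0.239 with an estimated correlation). Of contractile genes 11 of 24 were higher (15 were higher adjusted over the list alone, camera adjusted p = 4.51e-08, adjusted p = 0.246 with an estimated correlation). Of matrix proteases 16 of 25 were higher (17 were higher adjusted over the list alone, camera adjusted p = 2.72e-12, adjusted p = 0.239 with an estimated correlation). Of fibroblast markers 7 of 16 were higher (9 were higher adjusted over the list alone, camera adjusted p = 1.28e-08, adjusted p = 0.239 with an estimated correlation). Of NRF2 genes 17 of 34 were lower and 4 higher (21 were lower and 6 higher adjusted over the list alone, camera adjusted p = 2.17e-08, adjusted p = 0.239 with an estimated correlation). Of p53 targets 8 of 26 were lower (12 were lower and 1 higher adjusted over the list alone, camera adjusted p = 4.47e-06, adjusted p = 0.239 with an estimated correlation). Of integrated stress genes 9 of 34 were lower (13 were lower and 3 higher adjusted over the list alone, camera adjusted p = 8.29e-04, adjusted p = 0.246 with an estimated correlation). The tools disagreed on these, with 3 higher and 1 lower by edgeR and 2 higher and 6 lower by DESeq2. Of interferon genes 4 of 43 were higher and 1 lower (12 were higher and 2 lower adjusted over the list alone), with a median difference of 0.33 (camera adjusted p = 6.24e-04, adjusted p = 0.699 with an estimated correlation), and camera adjusted p = 0.237 without THOC5 growth replicate 2. By edgeR 11 of these were higher and 2 lower, and by DESeq2 9 and 1.

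By limma 2082 genes passed the interaction, of which 1197 were higher and 885 lower, and 2012 were genes of the GFP response (42.8% of it) with the opposite sign. Scaled to library totals, 2268 passed with 886 higher and 1382 lower, and the median of all genes moved by -0.110. Without GFP growth replicate 1 limma called 0 interactions, the genes named above included, with 5060 at an unadjusted p under 0.05 and 2453 by edgeR. The count was 103 without GFP growth replicate 2, 612 without GFP osteogenic replicate 1, 778 without THOC5 growth replicate 1, 796 without THOC5 osteogenic replicate 1 and 366 without THOC5 osteogenic replicate 2, and 1122 with any value above 0.

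**Figure D4:**
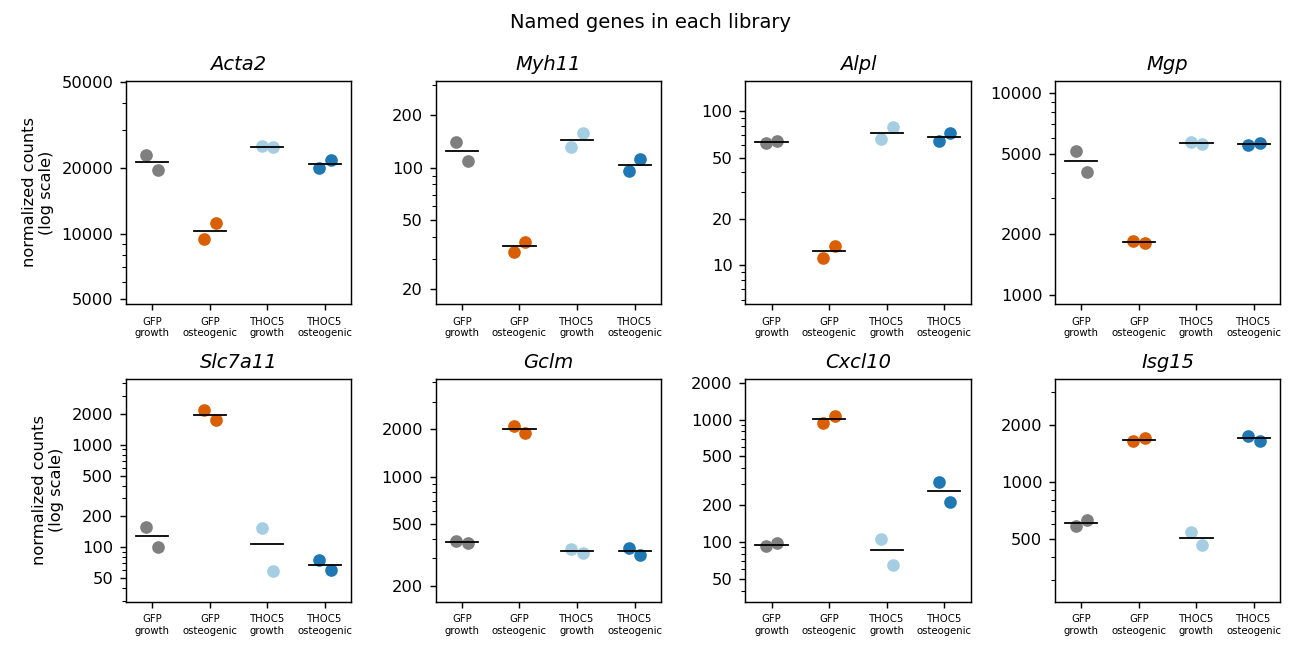
Normalized counts (log scale) of 8 named genes in each library (points) by group, with the group mean as a line. Acta2, Myh11, Alpl and Mgp were lowest and Slc7a11, Gclm and Cxcl10 highest in both GFP osteogenic libraries, while Isg15 was raised in osteogenic medium in both kinds of cell.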

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

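The tests on depth and on transcript length and GC content were written down before their results, and the other tests in this part were chosen only after the result was seen. What singled out each value here is the test of the difference between both kinds of cell in their response to osteogenic medium, which 2082 genes passed. Every value is the THOC5 response minus the GFP response on the log2 scale, and for a list it is the median over its members, with camera at the preset correlation.

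Lists whose fall in GFP cells was smaller or absent in THOC5 cells gave 0.94 for extracellular matrix genes, 1.02 for adventitial fibroblast markers, 0.72 for matrix proteases, 0.54 for contractile genes, 0.50 for calcification inhibitors and 0.39 for TGF-beta targets. The same sign was found for cell cycle genes at 0.43, hypoxia genes at 0.38, modulated smooth muscle markers at 0.37, Wnt genes at 0.35, senescence genes at 0.33, interferon genes at 0.33, NF-kB genes at 0.22 and ion channel genes at 0.12. With an estimated correlation 0 of these lists passed camera, and of hypoxia genes edgeR and DESeq2 called 0. With some library left out, camera at the preset correlation no longer passed for calcification inhibitors or for cell cycle, hypoxia, Wnt, interferon, NF-kB and ion channel genes. Negative differences were found for NRF2 genes at -0.79, integrated stress genes at -0.43, p53 targets at -0.33, nuclear oxidative phosphorylation genes at -0.24, and export, mRNA decay and ribosomal protein genes at -0.21 each, of which 0 passed with an estimated correlation. Of integrated stress genes, edgeR called 3 higher and 1 lower. Single genes were Acta2 at 0.79, Myh11 at 1.32, Cnn1 at 1.06, Alpl at 2.18, Mgp at 1.31, A2m at 5.22, Clca3a2 at 4.57, Serpina3i at 3.92, Kif26b at 3.79 and Hp at 3.50. Lower in THOC5 cells were Slc7a11 at -4.44, Atf3 at -2.81, Gsta3 at -2.66 and Psph at -2.49, and 93 further named list members passed the test of the difference.

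The pattern most open to a technical reading is that the GFP osteogenic libraries stood apart from the other 6. With every library thinned to 7058681 reads, 3811 genes still passed in the GFP response and 3696 of the original calls were kept, which speaks against depth as the whole cause. After a trend on transcript length and GC content was removed, 4958 passed (4647 among the same genes before, 3968 kept in both), which speaks against such a bias as the whole cause. A lower share of fibroblast-like cells would have raised the contractile genes, whose median was -0.70, only if those cells carry few contractile transcripts. That was not tested, so this median cannot decide on a change in the shares of cells. The labels name no batch or dish, so a handling difference of the GFP osteogenic dishes and the effect of the group cannot be told apart, and the effect of the medium itself stays open as the biological reading.

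The pattern of most interest to the study's question is a GFP response that was, outside the interferon list, mostly smaller or absent in THOC5 cells. A wrong label, with growth-medium cells under the THOC5 osteogenic name, is argued against by the interferon list, which had a median rise of 1.30 in those libraries. A response of equal size measured less precisely would give a ratio near 1. Over 517 to 1000 genes outside the interferon list, chosen by a 2-fold change in 1 pair of GFP libraries and sized in the other pair, the ratio of the mean THOC5 to the mean GFP change had a median of 0.113 (-0.0395 to 0.216 over all splits of the libraries). Of the 4660 GFP response genes outside that list 55.1% had the same sign in both responses (48.4 to 62.9% with 1 library left out). That lies below the share taken as a sign of a weaker exposure and above the share taken against it. By its median the interferon list did not respond less in THOC5 cells, with a ratio of 1.31 to the GFP change. Singly, 4 members passed the interaction upward and 1 downward, Ccl5, with log2 changes of 2.29 in GFP and 1.46 in THOC5 cells. The list also started lower in THOC5 cells in growth medium, mostly in replicate 2. In osteogenic medium it differed between both kinds of cell by a median of 0.0725. A weaker effect of phosphate in the THOC5 dishes for a reason other than THOC5 cannot be told apart from an effect of THOC5. Each group was 1 pair of libraries, and no group separates these causes. That THOC5 limits the loss of contractile and matrix transcripts in osteogenic medium is therefore only a hypothesis. The test of the difference, at 0.54 and 0.94 for those lists, prompted this hypothesis and is no separate support for it. Cultures transduced and treated separately would be needed to decide it.

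Interferon genes were higher in osteogenic medium in both kinds of cell, which was weighed against admixed macrophages and against the Ifnb1 transcript. The macrophage markers that rose gained 204 normalized counts in sum in GFP cells and 122 in THOC5 cells, with Mpeg1 in both, and Cd68 and Cd53 (6.66 to 27.7) in GFP cells alone, beside gains of 39635 and 45533 for the interferon list. The higher share, 0.514%, argues against admixed macrophages as the source of the interferon-list transcripts, since they would bring all their abundant transcripts. It cannot decide whether a few macrophages acted on the muscle cells, because that would need few macrophage transcripts. Other immune cells were not tested. Ifnb1, which encodes interferon beta, was lower in THOC5 cells in osteogenic medium, a call lost when single libraries were left out. The interferon list differed by a median of 0.0725 (-0.10 when scaled to library totals) between both kinds of cell, with 3 members higher and 6 lower, Oasl1 (-2.30), Cxcl10 (-1.96) and Rsad2 (-1.54) among them. Since members went both ways, a part played by the level of Ifnb1 cannot be told apart from other inducers. A response to nucleic acid or to another interferon was not tested and stays among the possible explanations.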

How the results depend on the processing

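Tests by edgeR and DESeq2, a minimum of 10, the removal of mitochondrial and ribosomal RNA genes and a replicate block within growth medium were chosen only after the data were seen. Of 738 results for named genes, 402 passed, of which 195 kept direction and threshold in every alternative, 207 lost the threshold in at least 1 and 0 changed sign. Another 336 did not pass, of which 42 passed in at least 1 alternative and 36 changed sign. Counts are in the order GFP response, THOC5 response, THOC5 in growth medium, THOC5 in osteogenic medium and interaction, and within 1.5 times of the 4698, 122, 1, 4963 and 2082 unless given. An absolute log2 change of at least 1 left 1239, 69, 1329 and 736 for all but growth medium, by construction. With any value above 0, the THOC5 response had 37, growth medium 0 and the interaction 1122, and with a pseudocount of 0.01 the THOC5 response had 59 and growth medium 0, and the cause was not tested. A fit of only the 4 libraries compared, with fewer degrees of freedom, gave 2293, 0, 0 and 3030. By edgeR, growth medium gave 4 with TMM and 4 with RLE factors. With 1 library left out, whose partner is assumed to vary like the other groups, counts ranged from 2067 to 4496, 8 to 106, 0 to 1, 1987 to 4753 and 0 to 1751 by limma, and the shared THOC5 effect of both media from 0 to 1. The same removals by edgeR gave 3465 to 5378, 87 to 191, 0 to 5, 3512 to 5950 and 1453 to 3134. Where limma gave 0 in growth medium, between 1024 and 1738 genes had an unadjusted p under 0.05, beside a share near 0.05 of tested genes expected with no difference.

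The log2 change of Thoc5 in growth medium ranged from 1.60 to 2.21 with 1 library left out, and its call was lost at 1.90 with any value above 0 and with only the 4 libraries, and at 1.91 with a pseudocount of 0.01. The median ratio of both osteogenic responses ranged from -0.00585 to 0.0820 with 1 library left out, and was 0.00857 over all tested genes. Camera with an estimated correlation called 0 lists in each of the 5 contrasts, and fry called 20, 4, 1, 19 and 17 against 21, 10, 12, 19 and 21 by camera with the preset correlation. Differences between replicates 1 and 2 correlated across genes at 0.402 between both growth groups and from -0.188 to 0.136 in the other pairs of groups, so the numbers were not taken to pair all samples. With the replicate block the counts were 4723, 123, 1, 4948 and 2238, and 22, 11, 12, 19 and 21 lists passed. With the replicate block within growth medium only, they were 5250, 140, 1, 5530 and 2737, with 24, 12, 12, 19 and 22 lists. It added the Notch, cell cycle and hypoxia lists in the GFP response, the integrated stress and mesothelial lists in the THOC5 response and the cholesterol list in the interaction, and ended no list's call. Both checks of pairing rest on which THOC5 growth library is called replicate 1, which the column names leave unclear. Depth limits genes near 3 reads, and replicates differed beyond counting noise, with chi-square per degree of freedom from 2.74 to 8.50. A 1.5-fold change in the interaction was recovered for 16.4% of simulated genes above the floor, in a simulation with 132 calls. The real interaction had 2082, so this share does not carry over, and smaller differences of response may still be missed at this size.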

Other observations

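Genes in this part were chosen after their values were seen, and the tests on them are those of the limma fit already described. The mitochondrially encoded ribosomal RNAs parted from the mitochondrial protein genes. In GFP cells mt-Rnr1 rose 3.24-fold in osteogenic medium, from 5354 ± 325 to 17402 ± 1850 normalized counts (adjusted p = 3.51e-06), and mt-Rnr2 rose 1.47-fold (adjusted p = 0.00151), while 5 of 8 mitochondrially encoded list genes fell. In THOC5 cells neither passed, with log2 changes of 0.18 ± 0.10 and -0.23 ± 0.09, and the interaction for mt-Rnr1 was -1.51 ± 0.15 (adjusted p = 3.29e-04, and 0.0514 without GFP growth replicate 1).

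Inflammatory enzymes went in opposite directions in GFP cells. Ptgs2, the inducible cyclooxygenase, rose 3.10-fold (adjusted p = 9.09e-06), and Nos2, the inducible nitric oxide synthase, fell 4.81-fold (adjusted p = 0.00812), from 1245 ± 874 to 229 ± 67.0. Nos2 varied widely between growth replicates, at 627 and 1864 in GFP cells and 392 and 1181 in THOC5 cells. Nfe2l2, which encodes NRF2 itself, rose 1.45-fold (adjusted p = 7.95e-04). Ifnb1 had 2 and 0 reads in GFP cells in growth medium and 31 and 44 in osteogenic medium (adjusted p = 0.00162, and 0.124 with a pseudocount of 0.01), and 2 and 0 against 5 and 9 in THOC5 cells (adjusted p = 0.694). Its difference between THOC5 and GFP cells in osteogenic medium had an adjusted p of 0.0445, which was 0.157 and 0.230 without GFP osteogenic replicate 1 or 2, 0.249 and 0.126 without THOC5 osteogenic replicate 1 or 2, and 0.0577 and 0.0558 without GFP growth replicate 1 or 2. Ifi27 fell in both kinds of cell, by 0.70 and 1.44 on the log2 scale, while the interferon list rose.

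Some lists differed in the same way between the growth-medium replicates of both kinds of cell, and others did not. Replicate 1 was below replicate 2 by a median log2 difference of -0.45 and -0.42 for hypoxia genes in GFP and THOC5 cells, -0.48 and -0.38 for cell cycle genes, and -0.22 and -0.44 for cholesterol genes. In the osteogenic groups the hypoxia differences were 0.05 and 0.02. The stress genes Chac1 (368 and 79.8 normalized counts in GFP cells, 363 and 58.3 in THOC5 cells), Mthfd2 (500 and 152, 604 and 137) and Trib3 (375 and 152, 358 and 118) were higher in replicate 1 of both. The interferon list differed by -0.11 in GFP and 0.36 in THOC5 cells, and the integrated stress list by 0.44 and 0.05. The labels do not say what the replicates of a number shared.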
